A study of Mus musculus with 4 samples.

How the data were processed

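The samples were 4 RNA pools from sorted mVenus-positive cells of mouse genital ridges at embryonic day 11.5, 2 of wild-type and 2 of HP1γ-null embryos, grouped by the genotype in the labels. Per the labels, 4 ng of total RNA per pool was amplified and labelled with Cy3 by a low-input kit, with diluted control RNA spiked in. Amplification from so little RNA can add noise for weakly expressed genes. Each pool was hybridised to 1 Agilent one-colour array. Per the file headers, the intensity values were extracted from the scans with Agilent Feature Extraction 10.7.3.1, which subtracted the background and removed spatial trends within each array, with no scaling between arrays. The authors' deposited value table holds linear intensity values that equal the processed signal rounded to 3 digits, differing from it by at most 0.50%. Its column medians were 20.6, 22.6, 14.5 and 33.4 for wild-type replicates 1 and 2 and null replicates 1 and 2, so its scale and direction are known and it was not centred. The replicates are separate embryo pools according to the labels. All arrays lay on 1 slide and were scanned once, so neither slide nor scan separates the groups.

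Computed here were log2 values of the processed signal, minus the array's own 75th percentile over the 43379 spots that are not controls. Spots of 1 probe were averaged on the log2 scale, and spots with an outlier mark from the scanner software (83 to 104 per array) were left out, which removed 21 of 41174 probes. Each array had 1 saturated spot, which was kept. Tested were the 22440 probes well above background on both arrays of at least 1 genotype. Per array, 53.3%, 56.7%, 53.8% and 63.3% of the spots were well above background in the order above. Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without a trend, two-sided, Benjamini-Hochberg over all tested probes, threshold 0.05), with no covariate. The files were read with Python 3.11.15 and pandas 2.3.3. The fit had 2 residual degrees of freedom per probe and a prior of 2.43. The spread shared across probes is wide because the null replicates differed by an SD of 0.84 on the log2 scale and the wild-type replicates by 0.40. Beside the test, probes were counted whose means differ at least 2-fold and whose arrays do not overlap between genotypes. Where a probe was not well above background on any array of 1 group, the fold is a bound. It sets the brighter group's mean against the mean, in the dimmer group, of the higher of the probe's own signal and the lowest signal among probes well above background on that array.

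The files name probes by accession only. Accessions were matched without versions to RefSeq names of assembly GRCm38.p6, which named 26888 of 41174 probes (18327 genes). The other 14286 were tested under their probe names. The array design was built on another assembly, so no coordinates are given. Where a gene had several probes, the one with the highest mean over the 4 arrays was used, chosen without regard to genotype.

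Before the data were examined, the test, the alternatives, 22 gene lists and the rule for named genes were fixed. The lists were germ cell identity, pluripotency, later germ cell genes, G1/S and replication, G2 and mitosis, G1 regulators, p53 targets, apoptosis, heterochromatin, Hox, imprinted, 2-cell-like state and Cbx3 neighbours. Further lists held markers of gonadal soma, mesonephros, stroma, endothelium, erythroid cells and leukocytes, and Y-linked, dissociation stress and ribosomal protein genes. A gene may stand in 2 lists, as Dcn does in the stromal and imprinted lists and Apaf1 in the p53 and apoptosis lists. Lists with at least 5 tested genes (21 of them) were compared with the other named genes by limma's camera with a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 21 lists. Camera with an estimated correlation and fry were run beside it. Named genes are Cbx3, Cbx1, Cbx5 and Hnrnpa2b1. To these come 10 genes in each direction by size among probes past the threshold without overlap, filled by unadjusted p from probes at least 2-fold apart without overlap where fewer pass. From each list come up to 4 members past the threshold, otherwise the 2 with the smallest unadjusted p, and as levels Xist, Prdm1, Pou5f1, Ddx4, Dppa3 and Kit. Clone, RIKEN, Gm and LOC names were passed over.

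The script was tested on simulated log2 values for the comparison of 2 wild-type with 2 null arrays, with 200 changed probes in each of 10 runs on 22440 probes. It recovered 0% of 2-fold, 6.6% of 4-fold, 80.8% of 16-fold and 93.6% of 64-fold changes, and 4.43% of its calls were false. Of simulated lists of 15 genes shifted by 0.5 on the log2 scale, 100% were called, and 1% of unshifted lists were. Genes were independent in these simulated data, and the real arrays differ more within the null group.

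Alternatives were quantile normalization, the median of probes well above background on all arrays, scaling to 7 spiked-in control probes, and normexp background correction (offset 50) with the 75th percentile or quantile normalization. Further ones were the authors' value table, no filter on dim probes, a filter on all 4 arrays, a threshold of 0.10, eBayes with a trend and with a robust trend, the replicate number as a block, each array left out in turn, and the mean of all probes of a gene. The scanner files hold no mean signal, so normexp was run on the median spot signal and the median local background. Leaving out an array leaves 1 pool in a group, which is then assumed to vary like the pools of the other group. The preset correlation also treats genes that move together on that pool as nearly independent. A list that passes in such a fit is therefore no measure of the spread between pools.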

Results

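The series measured gene expression in sorted mouse cells labelled as primordial germ cells, the embryonic precursors of eggs and sperm, with and without HP1γ. HP1γ, the product of Cbx3, is a heterochromatin protein that binds methylated histone H3. The null allele came from a gene trap. Embryos carried an mVenus reporter for Blimp1 (Prdm1), a regulator of germ cell fate, and mVenus-positive cells were sorted by flow cytometry from genital ridges at embryonic day 11.5. RNA was pooled from 5 to 6 embryos of 1 genotype, with 500 to 3500 sorted cells per embryo. There were 2 independent pools per genotype, giving 4 one-colour Agilent arrays on 1 slide. The 75th percentile of the processed signal was 188 and 219 intensity units on the wild-type arrays and 125 and 291 on the HP1γ-null arrays. Between 53.3% and 63.3% of the spots on an array were well above background, the highest share being that of HP1γ-null replicate 2. Across the 22440 probes tested, log2 signals of the wild-type replicates correlated at r = 0.988, those of the null replicates at 0.943, and arrays of different genotype at 0.953 to 0.960. These correlations are across probes, which are not independent replicates. Of 30 germ cell identity and pluripotency genes tested, 8 that ranged widely over the arrays were not well above background in null replicate 2. How far that pool holds germ cells is therefore open, and it enters every difference between genotypes given here. The small number of arrays limits the precision of every value below. Levels are log2 signals relative to the array's own 75th percentile, as mean ± SD of 2 pools. In wild-type replicates 1 and 2 and null replicates 1 and 2, the 17 pluripotency genes had median levels of -1.62, -2.95, 0.75 and -3.35. Those of the 14 endothelial genes were 4.57, 4.68, 3.93 and 4.15, and of the 12 leukocyte genes 3.59, 3.94, 3.67 and 3.83. Levels of different probes are not strictly comparable, but endothelial and leukocyte genes were bright in every pool. No difference can therefore be assigned to germ cells alone.

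The first question was whether the targeted gene was lost in the pools labelled null. Cbx3 was far lower in both null pools by each of its probes. By probe A_51_P160328 it fell from 4.93 ± 0.19 in wild type to -1.77 ± 0.26 in the null pools (n = 2 each). That is a log2 difference of -6.70 with SE 0.24, or 104-fold, and it passed the threshold (limma adjusted p = 0.044). Without wild-type replicate 1 or 2 or null replicate 1 or 2 it was -6.84, -6.57, -6.52 and -6.88, and the call was lost (adjusted p = 0.20, 0.18, 0.081 and 0.068). By the brighter probe A_51_P117162 the levels were 5.80 ± 0.12 and -2.01 ± 1.09, a 225-fold difference that missed the threshold (limma adjusted p = 0.099). The null replicates read -1.24 and -2.78 on that probe, so its spread was wider, and without null replicate 1 or 2 the log2 difference was -8.59 and -7.05. Signal from both probes remained well above background on both null arrays, and where they lie relative to the trap is not given in the sources used here. Its paralogs Cbx1 (HP1β) and Cbx5 (HP1α) differed by -0.28 and -0.26 on the log2 scale (limma adjusted p = 0.92 and 0.91), and further probes of Cbx5 went the other way, by 0.40 and 0.16. Without null replicate 2 Cbx1 differed by 0.14, and without null replicate 1 Cbx5 differed by 0.07. The neighbouring gene Hnrnpa2b1, which encodes an RNA-binding protein, differed by -0.34 (adjusted p = 0.81).

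**Figure D1:**
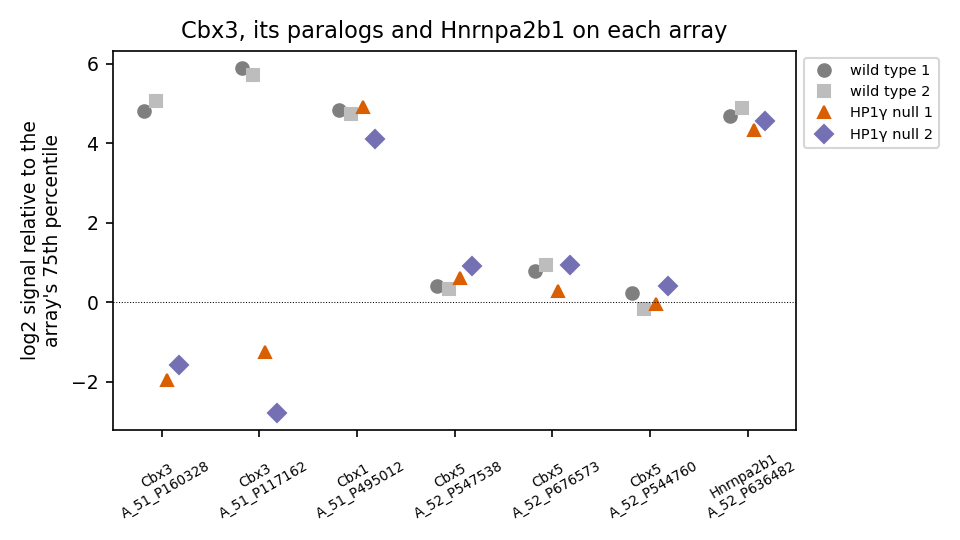
Levels of every tested probe of Cbx3, Cbx1, Cbx5 and Hnrnpa2b1 on each of the 4 arrays; the y axis is log2 signal relative to the array's 75th percentile and each symbol is 1 pool. Both Cbx3 probes lie between 4.80 and 5.89 in wild type and between -2.78 and -1.24 in the null pools, while the levels of the other genes lie much closer together.

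The second question was which other transcripts differed in cells lacking HP1γ. Apart from Cbx3, 1 probe passed the threshold and was lower in the null pools. This probe, A_51_P289423, has no gene name here and was at least 80.6-fold lower in the null pools, where it was not well above background (limma adjusted p = 0.025). With 1 array left out its adjusted p lay between 0.062 and 0.19, and with normexp background correction, which adds an offset that draws dim signals together, its fitted log2 difference was -3.62 (adjusted p = 0.056, and 0.0072 with quantile normalization). In all, limma called 2 of 22440 probes, none higher and 2 lower, while 1685 had an unadjusted p under 0.05 against 1122 expected by chance. At an adjusted p under 0.10 there were 17 probes, 11 higher and 6 lower, of which 8 carry no gene symbol. Without any 1 of the 4 arrays the count was 0, with 607 to 5644 probes at an unadjusted p under 0.05. In simulated data of this size the same test recovered 0% of 2-fold changes, 6.6% of 4-fold changes and 80.8% of 16-fold changes.

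As a description beside the test, 1120 probes differed at least 2-fold with no overlap between the genotypes, 879 of them higher and 241 lower in the null pools. Non-overlap alone was met by 38.2% of all probes, where chance gives 33.3%. The count was 2052 without null replicate 1, 1212 higher and 840 lower, and 2042 without null replicate 2, 1286 higher and 756 lower. The share higher was thus 78.5% with all arrays and 59.1% and 63.0% without those pools. A single null array avoids overlap more easily than 2, so these counts and shares are not strictly comparable with those of all arrays. Scaling to the spiked-in control RNA gave 422 higher and 2560 lower, because it moved the median difference of all probes from -0.06 to -0.61. None of the following genes, higher in the null pools, passed the threshold, and they were taken by unadjusted p. Dact2, a modulator of Wnt signalling, had levels of -2.36 ± 0.15 in wild type and 1.09 ± 0.16 in the null pools (limma adjusted p = 0.099). The other 9 genes were not well above background on either wild-type array by the probe used, so only lower bounds can be given. The collagen gene Col22a1 was at least 7.92-fold higher, the ubiquitin ligase gene Marchf9 at least 6.35-fold, the septin gene Septin3 at least 2.93-fold and the desmosomal cadherin gene Dsg2 at least 3.85-fold. The potassium channel gene Kcnt1 was at least 4.80-fold higher (limma adjusted p = 0.099 for each of these 5 genes). However, another Kcnt1 probe was well above background in wild type, though not on both wild-type arrays. Ppp2r2b, which encodes a phosphatase subunit, was at least 6.41-fold higher, the sialyltransferase gene St6galnac5 at least 2.44-fold, the steroid dehydrogenase gene Hsd3b1 at least 2.06-fold and Lrrn4 at least 2.70-fold (adjusted p = 0.11 for each). The 3 further probes of Dsg2 and the further probe of St6galnac5 pointed the same way. Further probes of Dact2, Septin3, Kcnt1 and Ppp2r2b were not tested, being well above background on both arrays of neither genotype.

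Among genes lower in the null pools, the macrophage scavenger receptor gene Cd163 had levels of -1.50 ± 0.35 in wild type and -4.25 ± 0.17 in the null pools, where 1 of the 2 arrays measured it (limma adjusted p = 0.13). The chemokine gene Cxcl16 had -1.59 ± 0.13 and -3.18 ± 0.19 (adjusted p = 0.24). The transcription factor gene Tcf15 had 4.04 ± 0.05 and 2.88 ± 0.18 (adjusted p = 0.37). Hmcn1, an extracellular matrix gene, had -2.20 ± 0.15 and -3.48 ± 0.14, and the ceruloplasmin gene Cp had -2.03 ± 0.27 and -4.16 ± 0.61, each measured on 1 of the 2 null arrays (adjusted p = 0.34 and 0.36). Tmem71 was at least 2.69-fold lower, Vwa5b1 at least 3.44-fold, the immune adaptor gene Sh2d1b1 at least 2.29-fold and the metalloproteinase gene Mmp28 at least 1.69-fold (adjusted p = 0.19, 0.31, 0.28 and 0.44). Without null replicate 2 these bounds were 1.78, 2.21, 1.47 and 1.08 for Tmem71, Vwa5b1, Sh2d1b1 and Mmp28. None of these 9 genes passed the threshold, and Cbx3 is the tenth by the same rule.

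Of the 30 germ cell identity and pluripotency genes tested, 20 ranged over more than 2 log2 units across the arrays, while 4 were higher and 3 lower in both null pools than in both wild-type pools. The germ cell marker Dppa3 read 1.60 and -0.26 on the wild-type arrays and 3.58 on the array of null replicate 1, and was not well above background in null replicate 2, where its signal was -7.04. Pou5f1, the pluripotency factor Oct4, read -1.73, -3.34 and 0.92 on the same 3 arrays and was not well above background in null replicate 2. Ddx4, the germ cell helicase Vasa, read 0.19, -1.32 and 0.66, and was likewise not well above background there. By contrast Prdm1, the gene of the reporter, read 1.25 ± 0.02 in wild type and 1.06 ± 0.59 in the null pools (limma adjusted p = 0.95). Kit had no named probe here.

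None of the 3 germ cell lists shifted as a group, and limma called no member over all probes. Among the 13 genes of germ cell identity measured, 7 were higher and 6 lower in the null pools, with a median of 0.28. Ifitm1 differed by 1.35 and Pecam1, which endothelial cells also express, by -0.78 (limma adjusted p = 0.68 and 0.63). Of 17 pluripotency genes, 9 were higher and 8 lower, with a median of 0.04. Klf4 differed by -0.77 and Klf5 by 1.78 (adjusted p = 0.53 and 0.72), Klf5 by 0.67 without null replicate 1 and 2.90 without null replicate 2. Of 11 genes of later germ cells, 4 were higher and 7 lower, with a median of -0.38. Rec8, a meiotic cohesin gene, differed by 1.69 with SE 0.22, and Tdrd1, of the piRNA pathway, by 1.20 with SE 0.42 (adjusted p = 0.20 and 0.64). Adjusted over the list alone, 1 later germ cell gene (Rec8) passed, and none of the other 2 lists did. There were 1, 1 and 2 members at an unadjusted p under 0.05. The camera adjusted p was 0.86 for each of the 3 lists. These lists turned with the null array used: the pluripotency median was -1.42 without null replicate 1 and 2.90 without null replicate 2. For germ cell identity the same medians were -0.54 and 1.05. The median of the later germ cell genes was -1.49 without null replicate 1 and 0.59 without null replicate 2.

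**Figure D2:**
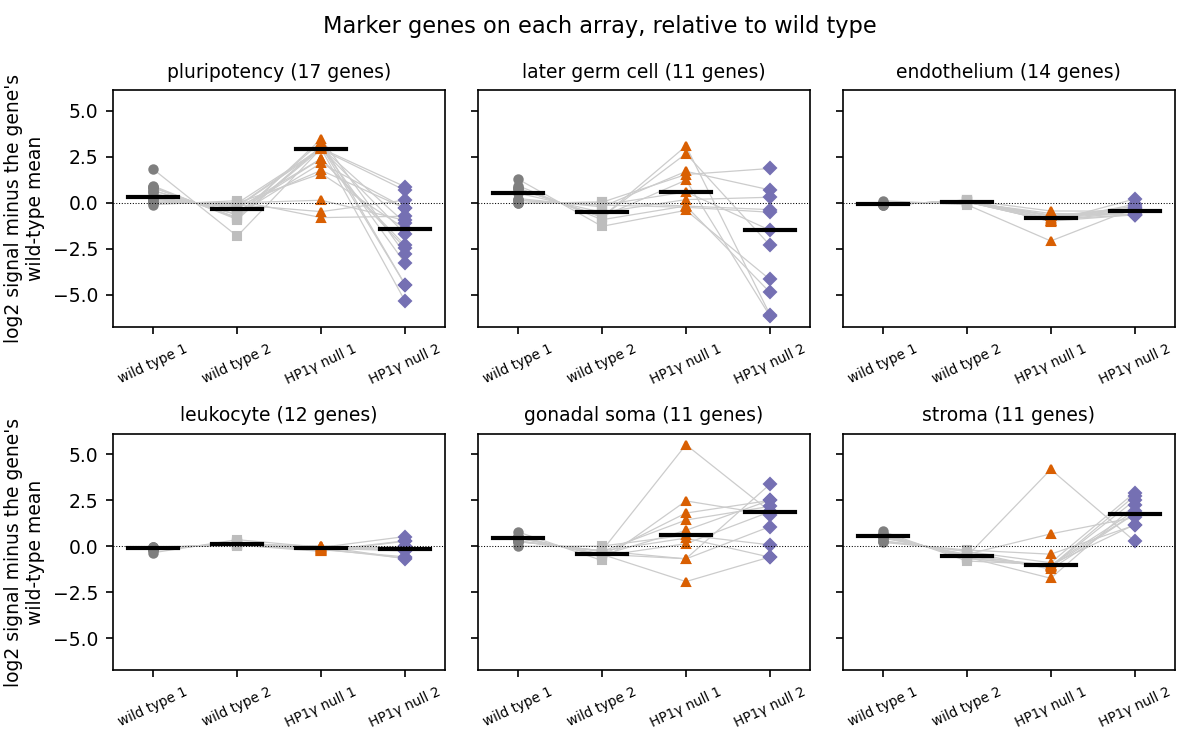
Log2 signal of the tested genes of 6 lists on each array, minus the same gene's wild-type mean; points are genes, grey lines join the points of 1 gene, and black bars are medians over the genes. Most of the 17 pluripotency genes lie highest on the array of null replicate 1, and their median is lowest on that of null replicate 2, while the 14 endothelial genes lie below wild type on most of the null points and the 12 leukocyte genes stay near 0.

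Markers of other cell types were measured in the same sorted pools. Endothelial genes fell as a group in the null pools. All 14 were lower, 13 of them on both null arrays, with a median log2 difference of -0.61 (camera adjusted p = 5.19e-08). The correlation estimated within this list was 0.60, far above the preset 0.01, so the preset form takes no full account of genes moving together. With an estimated correlation the camera adjusted p was 0.94, as for each of the 21 lists tested, so no list passed in that form. The vascular receptor gene Robo4 had levels of 6.38 ± 0.08 in wild type and 5.55 ± 0.24 in the null pools, and the endomucin gene Emcn 6.30 ± 0.07 and 5.51 ± 0.20 (limma adjusted p = 0.54 and 0.55). No single endothelial gene passed over all probes or adjusted over the list alone, and 6 had an unadjusted p under 0.05. Gonadal somatic genes rose as a group, 9 of the 11 measured being higher, with a median of 1.34 (camera adjusted p = 0.0056, and 0.94 as adjusted p with an estimated correlation). Amhr2, the receptor gene for anti-Müllerian hormone, had levels of -0.98 ± 0.68 and 1.16 ± 0.49, and Wnt4, a signalling gene of the early gonad, was at least 3.02-fold higher (limma adjusted p = 0.45 for each). These 2 genes passed adjusted over the list alone, none passed over all probes, and 4 had an unadjusted p under 0.05. Without null replicate 2 the gonadal median was 0.60 and the call was lost (camera adjusted p = 0.12).

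The remaining cell type lists did not pass. All 11 stromal genes had higher means in the null pools, with a median of 0.44 (camera adjusted p = 0.28), but the median level of these genes was -0.03 and -1.01 in wild type, -0.70 in null replicate 1 and 1.47 in null replicate 2. The median difference was -1.03 without null replicate 2, 1.77 without null replicate 1 and 1.02 without wild-type replicate 1. With all arrays the list passed under normexp and the 75th percentile (0.61, camera adjusted p = 0.010). As higher relative to the median of all probes of -0.61, it also passed under scaling to spiked-in RNA (-0.11, camera adjusted p = 0.00081). The collagen gene Col5a1 differed by 1.12 and Postn, a matrix gene, by 2.22 (limma adjusted p = 0.69 and 0.80). Postn read 1.94 in null replicate 1 and -1.96 in null replicate 2, opposite to most of the list, and differed by 0.27 without null replicate 1. Of 5 mesonephric genes 4 were higher, with a median of 0.26 (camera adjusted p = 0.55). Krt18, a keratin gene, differed by 3.22 with SE 0.64 (limma adjusted p = 0.44) and passed adjusted over the list alone. Without null replicate 1 or 2 it differed by 2.37 and 4.07. Cdh6, measured on 1 of the 2 null arrays, differed by -0.49. Of 12 leukocyte genes 10 were lower, with a median of -0.12 (camera adjusted p = 0.30). The macrophage genes Adgre1 and Mrc1 differed by -0.38 and -0.40. Of 5 erythroid genes 3 were lower, with a median of -0.03 (camera adjusted p = 0.86). The haemoglobin gene Hba-a1 differed by -0.34 and the erythropoietin receptor gene Epor by -0.15. Without null replicate 2 the erythroid median was -0.75, while without null replicate 1 it was 0.50, as was the difference of Hba-a1. Limma called no member of these 4 lists over all probes, and only Krt18 had an unadjusted p under 0.05.

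Imprinted genes rose as a group, 19 of the 27 measured being higher in the null pools, with a median of 0.30 (camera adjusted p = 0.026). The adjusted p was 0.94 with an estimated correlation. With scaling to spiked-in RNA the median was -0.25 and the median of all probes -0.61, so the list then stood higher only relative to other genes. Magel2 had levels of -3.21 ± 0.20 in wild type and -1.44 ± 0.30 in the null pools, and Usp29 was at least 2.71-fold higher (limma adjusted p = 0.26 and 0.30). Both passed adjusted over the list alone, none passed over all probes, and 6 had an unadjusted p under 0.05. Without null replicate 2 the median of the list was -0.09 and the call was lost (camera adjusted p = 0.90), while stromal genes were also highest in that pool. Of 25 Hox genes 18 were higher, with a median of 0.27 (camera adjusted p = 0.28). Without null replicate 1 this median was 0.58, and without null replicate 2 it was -0.11. Under scaling to spiked-in RNA it was -0.28 and passed as higher relative to the median of all probes, -0.61 (camera adjusted p = 0.042). Hoxb13 was at least 1.37-fold higher and Hoxa6 at least 2.04-fold (limma adjusted p = 0.17 and 0.58). Hoxb13 alone passed adjusted over the list, and 4 had an unadjusted p under 0.05. Of the genes of the 2-cell-like state only 2 were measured, too few for the list test. Tcstv1 read -2.61 and -4.17 in the null pools and was not well above background in wild type, at -4.81 and -4.21. Tcstv3, measured on 1 of the 2 wild-type arrays, differed by 0.62 (limma adjusted p = 0.77 for Tcstv1 and 0.69 for Tcstv3).

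**Figure D3:**
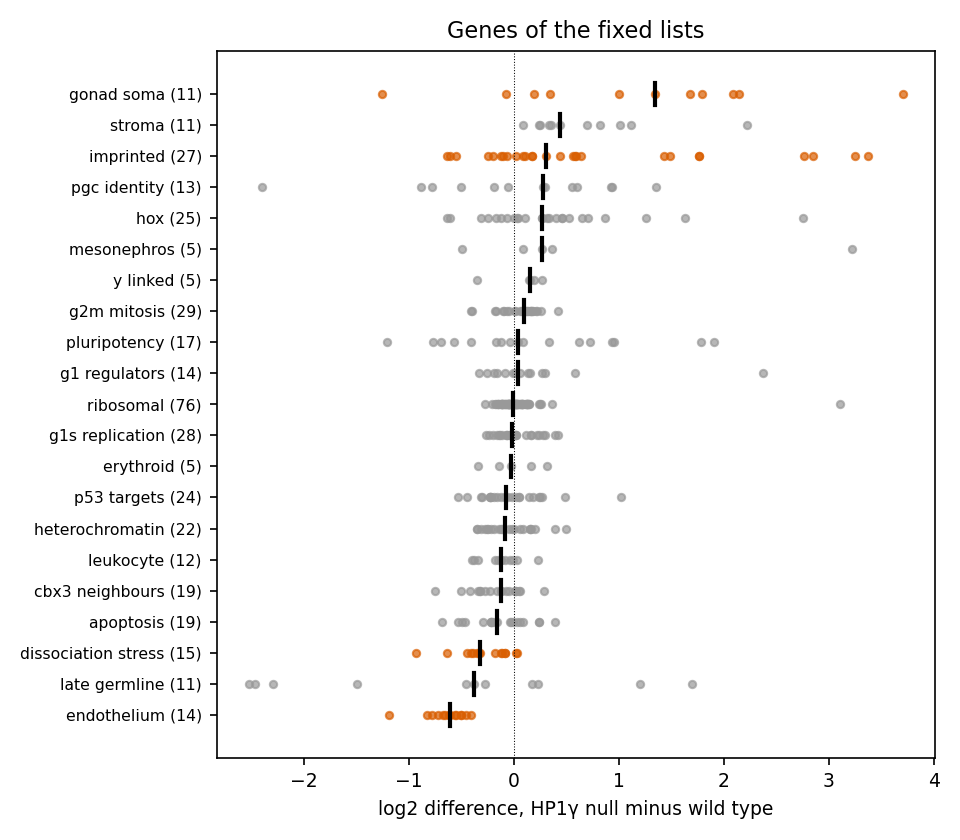
Log2 difference (HP1γ null minus wild type) of every tested gene of the lists with at least 5 tested genes; each point is 1 gene, the bar is the list's median and the number of genes follows the name. Orange lists passed camera with the preset correlation; endothelium (median -0.61) and gonadal soma (median 1.34) stand at the ends.

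None of the 6 lists of cell cycle, p53, apoptosis and chromatin genes passed, and their medians lay between -0.16 and 0.09. For 28 genes of the G1/S transition and DNA replication the median was -0.02 and the mean 0.03, and camera gave the direction of the mean (adjusted p = 0.86). Cdc45 differed by 0.39 and Ccne1 by 0.30. For 29 genes of G2 and mitosis the median was 0.09 (adjusted p = 0.55), with Ube2c at 0.42 and Cdc25c at -0.41, or 0.01 without null replicate 2. Without null replicate 2 this median was 0.28, and without null replicate 1 it was -0.17. For 14 regulators of G1 it was 0.04 (adjusted p = 0.86). Rb1 differed by -0.34. Cdkn2b, a cell cycle inhibitor gene, read -0.97 in null replicate 1 but -4.24 in null replicate 2, and was not well above background in wild type, at -4.91 and -5.05 (limma adjusted p = 0.74). For 24 p53 targets the median was -0.07 (camera adjusted p = 0.55), with Apaf1 at -0.53 and Rrm2b at -0.45. For 19 apoptosis genes it was -0.16 (adjusted p = 0.28), with Xiap at -0.69. For 22 heterochromatin and DNA methylation genes it was -0.08 (adjusted p = 0.86). Trim28, a corepressor gene, differed by 0.50 and Mbd2 by -0.35. None of the members named here passed over all probes or adjusted over the list alone, and none in these 6 lists had an unadjusted p under 0.05.

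Lists chosen as technical signs were measured in the same way. Genes of tissue dissociation stress fell as a group, 13 of 15 being lower in the null pools, with a median of -0.32 (camera adjusted p = 0.026). The adjusted p was 0.94 with an estimated correlation. Endothelial genes lay lower in the same pools, with a median of -0.61. Fosb differed by -0.93, measured on 1 of the 2 null arrays, or by -0.30 without null replicate 1, and Junb by -0.45. None passed over all probes or adjusted over the list alone, and none had an unadjusted p under 0.05. The call was lost without wild-type replicate 2, with a median of -0.23 (camera adjusted p = 0.26), and without null replicate 1, also at -0.23 (0.15). The 19 measured genes flanking Cbx3 had a median of -0.12 (camera adjusted p = 0.16), with Ccdc126 at -0.75 and Chn2 at -0.42, and Ccdc126 alone had an unadjusted p under 0.05. Without null replicate 1 the median of this list was -0.24, while without null replicate 2 it was 0.06 and the camera direction still lower. The 76 ribosomal protein genes had a median of -0.01 and a mean of 0.04, and camera gave the direction of the mean (adjusted p = 0.86). Rpl39l differed by 3.11 and Rpl29 by 0.26 (limma adjusted p = 0.47 and 0.85), and only Rpl39l had an unadjusted p under 0.05. It differed by 2.29 without null replicate 1 and by 3.92 without null replicate 2. None of the flanking, ribosomal or Y-linked genes passed over all probes or adjusted over the list alone. The ribosomal median was -0.27 without null replicate 1 and 0.23 without null replicate 2. As a sign of the sex mix of the pooled embryos, Xist read 3.82 ± 0.46 in wild type and 3.44 ± 0.28 in the null pools (limma adjusted p = 0.86). The 5 Y-linked genes measured had a median of 0.15 (camera adjusted p = 0.86), with Zfy2 at -0.36 (0.25 without null replicate 2) and Kdm5d at 0.26.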

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

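The alternatives were fixed before the data were examined. The count of changed probes, 2 by the main test, was 146 with scaling to the spiked-in RNA, 5 with normexp and quantile normalization, 0 with no filter on dim probes (1474 at an unadjusted p under 0.05), 1 with the filter on all arrays, 7 with a trend, 12 with a robust trend and 17 at an adjusted p under 0.10. It was 0 to 0 without any 1 array, where fewer degrees of freedom remain, and 2 or 3 under the others. With the replicate number as a block it was 13 probes, both main calls among them. The numbers give no ground for pairing: deviations of same-numbered arrays correlated at 0.07 across probes, and the labels tie no number to a litter or day. Probes at least 2-fold apart without overlap, 1120 in number, were 2982 with spiked-in RNA, 253 with normexp, 225 with normexp and quantile normalization, 2302 without a filter and 516 with the filter on all arrays, and 1238 to 2052 without 1 array. The share higher in the null pools, 78.5%, was 59.1% without null replicate 1, 63.0% without null replicate 2, 14.2% with spiked-in RNA and 89.3% and 91.1% with normexp and the 75th percentile or quantile normalization. Spiked-in scaling, like that to the 75th percentile, shifts all probes of an array together. It moved the median difference to -0.61 and the prior degrees of freedom from 2.43 to 15. With 1 array left out, non-overlap is met more easily than with all arrays.

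The brighter Cbx3 probe kept its direction under every alternative. Its difference passed the threshold with spiked-in RNA (-8.36), normexp (-6.60), normexp with quantile normalization (-6.51), a trend or a robust trend (-7.82 in both), the block (-7.82) and the mean of its probes (-7.26), with adjusted p from 1.61e-08 to 0.57 over all alternatives. The called Cbx3 probe lost its call with no filter (adjusted p = 0.38) and without any 1 array, and the called unnamed probe in the same settings (0.30 with no filter) and with normexp (0.056). The 4 gene lists past the threshold were 2 with the filter on all arrays, 0 with an estimated correlation, 0 with fry and 3 to 9 without 1 array, and 4 or 5 under the others, the block included (4). Endothelium kept its call under all 16 refits, with medians from -1.16 to -0.46, but not under the other 2 list tests. Gonadal soma kept it under 15, imprinted genes under 14 and dissociation stress under 12. The imprinted call was lost with the filter on all arrays, and dissociation stress also with spiked-in RNA and with that filter. Without null replicate 1 the medians of germ cell identity, pluripotency and ribosomal genes were -0.54, -1.42 and -0.27. Without null replicate 2 they were 1.05, 2.90 and 0.23, and imprinted genes turned to -0.088. Among 333 refits of single lists, 15 passed newly, 3 of them in the opposite direction, 7 lost the call, 1 of them also turning, and 28 changed direction without passing in either case. Among 1092 refits of single named genes, 20 passed the threshold newly, none of them in the opposite direction, and 22 that passed in neither case changed sign. The cause of these changes was not tested beyond what is stated. A block for slide or scan was not run, since there was 1 of each. Signal over background limits the dim probes: of the 22440 tested, 20320 were well above background on all 4 arrays.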

Other observations

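The genes in this paragraph and the next were chosen after their values were seen, and none passed the threshold. They are not given as evidence for any group, although Peg3, Dlk1 and Rian belong to the imprinted list and Krt8 to the epithelial markers below. Dsp, the desmoplakin gene, read -2.44 and -1.90 in wild type and 0.70 and 0.75 in the null pools on its brightest probe (limma adjusted p = 0.12). Fras1, of the Fraser complex, read -2.38 and -3.05 against -0.09 and 0.14 (adjusted p = 0.16). Krt8 read -2.19 and -2.02 against 2.61 and 1.09 (adjusted p = 0.24). Amph, the amphiphysin gene, read -2.07 and -2.76 against 1.93 and 3.22 (adjusted p = 0.16).

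Rsad2, the viperin gene, had levels of 2.28 ± 0.12 in wild type and 1.45 ± 0.47 in the null pools (limma adjusted p = 0.65). Lair1, an inhibitory leukocyte receptor gene, read 0.46 and 0.43 against -0.32 and -0.53 (adjusted p = 0.50). Cyp26b1, whose enzyme degrades retinoic acid, had 5.43 ± 0.10 against 3.99 ± 0.55 (adjusted p = 0.50). Of the imprinted genes, Peg3 read 1.41 and 1.10 against 2.06 and 3.42, while Dlk1 and Rian stood out in null replicate 2 at 3.66 and 3.68, against -0.57 and -0.39 in null replicate 1.

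Of the tests that follow, those of the spread of germ cell markers and of endothelial markers, and the test of scaling for the excess of higher probes, were chosen after the results were seen. The tests on dim spots, on other splits of the arrays and on epithelial markers were written before their own results were seen, but the epithelial list was drawn up after Krt18, Krt19, Dsg2 and Dsp had been seen higher in the null pools.

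Germ cell markers spread widely over the arrays: of 30 tested identity and pluripotency genes, 20 ranged over more than 2 log2 units, and 15 of these were lowest in null replicate 2. A weak array does not account for it, since 63.25% of the spots of null replicate 2 were well above background, against at most 56.7% on any other array. In only 4 of the 30 genes did both null arrays lie on 1 side of both wild-type arrays, and in 3 on the opposite side. Genotype as the only cause leaves that gap between the null pools unexplained. These counts come from the values that gave the pattern, so they describe it and are no separate test. A different share of germ cells among the sorted cells may underlie the spread, since 18 of 30 genes shared 1 order of the arrays. The order ran from null replicate 1 through wild-type replicates 1 and 2 to null replicate 2. It was taken as the most common order after the values were seen. The genes also move together, with estimated correlations of 0.57 and 0.58 within the identity and pluripotency lists. The 1.25 genes expected for 1 order named beforehand and independent genes is therefore too low a measure of chance. A change of state in the same cells would give that order too and stays open, as does an effect of genotype on germ cell number that differed between pools.

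More 2-fold probes were higher than lower in the null pools. The floor of dim spots does not account for the share that was higher, since it was 79.07% of the 516 such probes well above background on all arrays. These were 408 higher and 108 lower, against 879 and 241 with the main filter. Part of the excess in number therefore lay in probes that were dim on some array. Scaling stays open: the share was 14.15% with spiked-in RNA, but that scaling shifts all probes of an array together and so sets the balance itself, and the share lay between 72.6% and 91.1% under the other scalings and at 59.1% without null replicate 1. The 4 arrays have only 3 splits into pairs, too few for a share under 0.05: among 23693 probes well above background on at least 2 arrays the real split separated 1181, the highest other 749, and only the real split, 1 of the 3, reached that count. Probes well above background on both null arrays and neither wild-type array numbered 465, against 29 the other way, but the split of null replicate 2 and wild-type replicate 2 from the other arrays gave 1008 and 30, so genotype and brightness both stay open.

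Endothelial markers were lower in the null pools, with leukocyte markers nearly level. Equal dilution of both marker sets by RNA of other cells alone is argued against, because the leukocyte median lay 0.49 above the endothelial one. A two-sided permutation test across the 26 genes, which are not independent replicates, gave p = 0.00013. That p measures the spread of genes and not of pools. Dilution by RNA that itself held leukocyte transcripts need not lower both sets equally, so the test cannot exclude it. Scaling is argued against too, since over the scalings the endothelial median was at highest -0.58, and never nearer than -0.52 to the median of all probes. A lower share of endothelial cells and lower expression within them stay open, and with 2 pools per genotype so does a difference between pools. Whether the sort on mVenus removes such cells was not tested, and the endothelial genes had median levels of 4.57 and 4.68 in wild-type replicates 1 and 2. In null replicates 1 and 2 these medians were 3.93 and 4.15, so endothelial transcripts remained in every pool.

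A further hypothesis was that the null pools held more epithelial cells. Whether the sort on mVenus removes these was not tested, and endothelial genes were bright in every pool after it. Of 22 epithelial markers, 2 of them also in other lists, 13 were tested, and 6 were higher in both null pools than in both wild-type pools, where chance gives 2.17, while 0 were lower. That count decides nothing, because Krt18 and Krt19 prompted the list and Krt8 was also picked by its value. Without these 3 keratin genes 3 of 10 were higher in both null pools, where chance gives 1.67, and the camera p was 0.0013, or 0.39 with an estimated correlation, so the hypothesis stays open. Cldn3, Cdh1, St14 and Marveld2 were lower in null replicate 2, at -3.22, -4.38, -1.68 and -3.11, than in both wild-type pools. Krt18 and Krt8 read 4.38 and 2.68, and 2.61 and 1.09, in the null pools, and Krt19 and Krt18 stand in the gonadal soma and mesonephros lists. Cdh1 and Epcam, which germ cells also express, were highest in null replicate 1 at 1.08 and 1.43 and read -4.38 and -3.19 in null replicate 2, like the germ cell markers.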
